A study of Anopheles gambiae with 3 samples.

How the data were processed

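RNA-seq was carried out on Ag55, a cell line of the malaria mosquito Anopheles gambiae, in 3 replicates that form a single group. Per the labels, RNA was extracted with TRIzol from cells at 80% confluency, the extraction was repeated for each replicate, and libraries were made with a stranded mRNA kit. The labels do not say whether the replicates came from separate cultures, so the authors' p-values may measure only technical spread. The labels describe no control or treatment.

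The authors deposited 3 tables from a Cufflinks and Cuffdiff run. Per the submitters' processing notes, the tools were FastQC, TopHat2 2.0.13, Cufflinks 2.2.1 and Cuffdiff. The genome build, the annotation version and the strand setting of the counting are not given in the sources used here. Overlapping genes on opposite strands may therefore share fragments. Per the file headers, Cuffdiff was run on Ag55 and on a condition named BF_Adult. No sample described in the labels used here belongs to BF_Adult. What its abbreviation stands for, how many libraries it holds and how they were made are not given in the sources used here. A difference between the conditions thus cannot be told apart from a difference between batches.

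The gene table gives the authors' FPKM (fragments per kilobase of transcript, scaled to the mapped fragments) for Ag55 as a single deposited value per locus, already pooled over the replicates. It also holds the authors' log2 ratio between the conditions and the Cuffdiff p-value and q-value of each locus, as deposited. The isoform table holds the same for transcripts. The remaining deposited table gives an estimated count per transcript for Ag55, with the variance of that count under the authors' model. Whether a pooled count is a sum or a mean over replicates is not given in the sources used here. The 6 columns of levels and counts of BF_Adult were not used, since they belong to no sample described here. Deposited ratios are expressed as Ag55 over BF_Adult unless stated otherwise.

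The planned tests assumed FPKM per replicate, and the tables used here hold pooled values. A locus was therefore called expressed from the pooled FPKM, at 1 or more. Agreement between replicates, differences between replicates, the genes that vary most between them and a mean with its standard deviation could not be computed. As the measure of error, the square root of the deposited count variance was divided by the estimated count (relative model SD). For a locus with several transcripts, counts and variances were summed as if the transcripts were independent. The estimated counts of Ag55 summed to 5766284 fragments, and the depth of each library is unknown. Over the 1473 loci with a single transcript and an estimated count of at least 100, the median relative model SD was 18.9%, with quartiles of 17.6% and 23.4%.

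The gene table lists 17089 loci. Left out were 20 loci with the status HIDATA (too many fragments) and 4 with the status FAIL, which Cuffdiff did not estimate. Among the former were all 6 mitochondrial loci. Of the 17065 loci used, 13241 carry at least 1 AGAP gene ID and 3824 carry none. In 716 loci more than 1 ID was merged, and the value then belongs to the merged locus. Starts are counted from 0 in the tables and were raised by 1. Coordinates of a locus are those of its bundle of overlapping transcripts, which neighbouring loci can share.

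The tables pair no ID with a gene name, and the reference table used for names (assembly idAnoGambNW_F1_1) holds no AGAP ID, so no ID matched it. Genes are therefore given by ID, without names. Before the data were examined, 25 gene lists were fixed, mostly by gene symbol, and 10 of them also by AGAP ID from knowledge of the mosquito gene set. Only these IDs could be used: 40 of 41 were found, in 41 loci. Their assignment to a list was not checked against an annotation, which limits every statement on a list. The other 15 lists, among them the cytochrome P450s, the gut proteases and the muscle genes, held no ID and were not analysed here. The rule for the genes to be named, fixed at the same time, was the 3 members of each list with the highest level, and up to 3 of those under 1 FPKM. Its part on the 10 genes of highest level needed gene names and was not applied. Other list members are named where a count is explained by them, and 4 further IDs were chosen after their values were seen.

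The level of a list was the median of log2(FPKM + 0.1) over its loci. It was set against 10000 random lists of the same size drawn from the 17065 loci (two-sided permutation over loci, Benjamini-Hochberg adjustment over 8 lists, which include the small RNA list and both its parts). The share of expressed loci in a list was compared with all other loci by a two-sided Fisher's exact test. The ratio to BF_Adult was tested against random lists of the 12357 loci that the authors tested. Lists under 3 loci are given as values. Of 7 planned contrasts between lists, 4 could be computed, by exact permutation of percentile ranks with Benjamini-Hochberg adjustment over these. These tests take genes as units, so their p-values describe the pooled values and not the spread between replicates. Against an estimated count under 1, a fold was computed at a floor of 3 fragments over the pooled group, which covers counting error only.

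Chromosome arms were compared by 2000 permutations of the loci over arms, adjusted over the 5 arms. Medians in windows of 2 Mb with at least 20 loci that carry an AGAP ID were compared with 2000 shuffles of the loci over positions. A single window was called where the standardised mean rank of its loci lay below -3.45 or above 3.48, limits set from the extreme windows of the shuffles. Infinite log2 ratios were limited to a size of 15 in the windows, a choice made after a first result was seen. The arm and window patterns were first noticed in an exploratory look at the same data. All comparisons with BF_Adult, by arm, by window and of loci without an ID were added after the data were examined.

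The list and window tests were tried on simulated data made from the same loci, and the exact permutation on uniform random values. With no shift, 3.0% of 100 random lists of 5 loci and 7.0% of 100 lists of 8 loci passed an unadjusted threshold of 0.05. With a shift of 4 log2 units, 49.0% and 66.0% did, and with 6 units 69.0% and 90.0%. Lists of this size thus show only large shifts. The exact permutation of 8 uniform random values against 5 called 7.0% of 200 simulations with no shift. It found a shift of 60 points in 94.5% of 200 simulations. Values shifted in this way can leave the range of percentile ranks, so that share does not give the power of the real contrast. In the window test, run on 8962 loci, a shift of 2 log2 units in a window of 79 loci was found in 98.0% of 50 simulations.

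Alternatives covered the FPKM threshold, the pseudocount, rescaling to TPM, estimated counts in place of FPKM, the background of the list tests, merged loci, the q threshold and the window size. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.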

Results

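Transcript levels were measured by RNA-seq in Ag55, a continuously growing cell line derived from the malaria mosquito Anopheles gambiae. The single group held 3 replicates, which the authors pooled into 1 value per locus, so values carry no SD over replicates. The estimated counts of Ag55 summed to 5766284 fragments over 32248 transcripts. The series title presents the line as a possible model for the meeting of mosquito and pathogen, and its design implies a description of what the cells express. The deposited tables add a comparison with a condition named BF_Adult, which the labels do not describe.

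Of the 17065 loci used, 9518 (55.8%) were expressed in Ag55 at 1 FPKM or more, of which 7111 carry an AGAP ID and 2407 do not. Levels of at least 100 FPKM were reached by 976 loci and levels of at least 1000 FPKM by 138, and 3716 loci were listed at 0. The 100 highest loci held 60.5% of the summed FPKM, and the 10 highest held 14.2%. By estimated counts these shares were 42.3% and 9.47%. The 20 loci with too many fragments to be estimated are left out of both. Mitochondrial transcripts were not estimated in the tables. Of 9392 loci with a transcript at 1 FPKM or more, 3001 (32.0%) had at least 2 such transcripts. In these, the major transcript held a median of 71.0% of the locus's FPKM. The number of loci with several expressed transcripts fell to 1513 at a threshold of 5 FPKM.

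Haemocytes are the circulating immune cells of the mosquito. Membership in this and the following lists was fixed by gene ID before the data were examined and was not checked against an annotation. In Ag55, 6 of the 8 loci of the haemocyte list were expressed, with a median of 70.5 FPKM over the list. AGAP000305 (X, 5401645 to 5423656) was highest at 1173 FPKM, with a relative model SD of 26.4%. The locus holding AGAP009762 (3R, 42451588 to 42470223), which merges 3 IDs, followed at 347 FPKM, and AGAP009200 (3R, 28612608 to 28654365) stood at 197 FPKM with a relative model SD of 42.4%. AGAP012386 (3L, 41415213 to 41432021) and AGAP007318 (2L, 45333309 to 45334372) were listed at 0. The list median lay at the 99.8th percentile of random lists (permutation test, p = 0.0040, adjusted p = 0.032). That call was lost without the merged locus (permutation test, adjusted p = 0.25) and against loci with an AGAP ID alone (permutation test, adjusted p = 0.086), with a range of 0.011 to 0.25 over 7 alternatives. The share of expressed loci, 75% against 55.8% elsewhere, did not pass Fisher's exact test (adjusted p = 0.64).

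Against BF_Adult, 5 of the 8 haemocyte loci were called higher in Ag55 and 1 lower in the authors' deposited table. Adjusted over the list alone, the counts from the authors' deposited table were also 5 and 1. AGAP000305 was 21.4-fold higher in Ag55 in the authors' deposited table (Cuffdiff q = 0.00012). The authors' deposited table gave 5.67-fold for AGAP028028, 5.38-fold for the locus of AGAP009762 and 4.57-fold for AGAP009201, each higher in Ag55 at that same q, the smallest in the table. For AGAP007045 it was 1.48-fold higher in the authors' deposited table (Cuffdiff q = 0.025). AGAP009200, which shares its span with AGAP009201, had a log2 ratio of -0.06 in the authors' deposited table and was not called (Cuffdiff q = 0.91). AGAP012386 was the locus called lower in the authors' deposited table. The median log2 ratio over the list, computed from the authors' deposited table, was 2.19 and did not pass against random lists (permutation test, adjusted p = 0.55). Without the merged locus that median from the authors' deposited table was 1.38.

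Of the 4 loci in the fat body and neuronal lists, 3 stood under 1 FPKM. The fat body list covers yolk and lipid carriers that this organ secretes. AGAP001826 (2R, 11116758 to 11163371) reached 1.83 FPKM, and the locus holding AGAP004203 (2R, 51712401 to 51792488), which merges 3 IDs, stood at 0.0043 FPKM. Both were called lower in Ag55 in the authors' deposited table, and remained so adjusted over the list alone. AGAP001826 was 108-fold lower in the authors' deposited table (Cuffdiff q = 0.00012). With a floor of 3 fragments, the locus of AGAP004203 was 235-fold lower, from the ratio in the authors' deposited table (Cuffdiff q = 0.011). That locus rested on an estimate of 0.15 fragments with a relative model SD of 1481%, so the fold is not a lower bound. The neuronal loci AGAP004707 (2L, 2357925 to 2431729) and AGAP001356 (2R, 3483270 to 3497871) stood at 0.049 and 0.080 FPKM, on estimates of 1.74 and 1.96 fragments. Both were called lower in the authors' deposited table (Cuffdiff q = 0.00012 and 0.00085) and also adjusted over the list alone, and no fold is given at that depth. Haemocyte loci ranked 33.6 percentile points above the fat body loci and 41.4 above the neuronal loci, and neither difference passed (exact permutation test, two-sided, p = 0.27 and adjusted p = 0.53 for each). With 8 loci against 2, the smallest unadjusted p that the exact permutation test allows is 0.022. Without merged loci the difference from the fat body loci was 15.3 points.

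The antimicrobial effector list was fixed to cover small secreted peptides that kill microbes. In Ag55, 3 of its 5 loci were expressed, led by AGAP000693 (X, 12440533 to 12441132) at 89.7 FPKM with a relative model SD of 18.9%. AGAP000694 (X, 12442174 to 12442986) stood at 72.3 FPKM and AGAP008645 (3R, 13896514 to 13897373) at 41.5 FPKM. AGAP000692 (X, 12437473 to 12438077) was listed at 0, and AGAP011294 (3L, 20627828 to 20628236) stood at 0.89 FPKM on an estimate of 0.75 fragments. In the authors' deposited table, 4 of the 5 loci were called lower in Ag55 than in BF_Adult and 0 higher, and adjusted over the list alone the counts were the same. AGAP008645 was 37.0-fold lower, AGAP000693 6.99-fold and AGAP000694 4.76-fold in the authors' deposited table (Cuffdiff q = 0.00012 each). AGAP011294 was not called in the authors' deposited table (Cuffdiff q = 0.28). The level of the list did not pass against random lists (permutation test, adjusted p = 0.12), but did with a background matched on genomic span (permutation test, adjusted p = 0.044, range 0.044 to 0.35 over 7 alternatives). Its median log2 ratio of -5.21, computed from the authors' deposited table, did not pass (permutation test, adjusted p = 0.55), and was the same with AGAP011294 set at the floor. The expressed share, 60%, did not pass Fisher's exact test either (adjusted p = 1).

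Pattern recognition genes encode proteins that bind microbes or parasites. Of the 7 loci on that list, 6 were expressed in Ag55. AGAP005203 (2L, 12198694 to 12208656) stood at 201 FPKM (relative model SD 25.9%), the locus holding AGAP010815 (3L, 11180760 to 11220099), which merges 3 IDs, at 170 FPKM, and AGAP006348 (2L, 30172577 to 30340895) at 63.8 FPKM. AGAP007036 (2L, 41270870 to 41272901) stood at 0.41 FPKM, on an estimate of 4.19 fragments with a relative model SD of 63.1%. The authors' deposited table called 5 loci lower in Ag55 and 1 higher, as did adjustment over the list alone. The exception was AGAP005203, 10.1-fold higher in Ag55 in the authors' deposited table (Cuffdiff q = 0.00012). The authors' deposited table gave 3.37-fold lower for AGAP006348 and 12.7-fold for the locus of AGAP010815 (Cuffdiff q = 0.00012 each). AGAP007036 was called lower in the authors' deposited table at the same q, and no fold is given at its depth. AGAP007033 lay in 2 overlapping loci. The locus that carries it alone had a log2 ratio of 0.07 and was not called, and the locus that merges it with AGAP007035 was 10.3-fold lower, in the authors' deposited table. The level (permutation test, adjusted p = 0.29), the ratio (permutation test, adjusted p = 0.64) and the expressed share of the list (Fisher's exact test, adjusted p = 0.28) did not pass.

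Loci of the immune signalling lists were called in both directions. All 3 loci of the list for IMD, a pathway of the response to bacteria, were expressed: AGAP005203 as above, AGAP006747 (2L, 37732931 to 37744772) at 57.9 FPKM and AGAP004959 (2L, 7194587 to 7195863) at 14.1 FPKM. In the authors' deposited table, 2 of these were called higher in Ag55 and 0 lower, with the same counts adjusted over the list alone. AGAP006747 was 1.82-fold higher in the authors' deposited table (Cuffdiff q = 0.00012), and AGAP004959 had a log2 ratio of -0.08 and was not called (Cuffdiff q = 0.74). In the Toll list, AGAP007938 (3R, 3214034 to 3222195) stood at 44.5 FPKM and was not called in the authors' deposited table (Cuffdiff q = 0.33). AGAP009515 (3R, 35054246 to 35091258) was split over 2 loci of the same span, at 10.5 and 0.029 FPKM. The former was called lower in Ag55 in the authors' deposited table (log2 ratio -1.998, Cuffdiff q = 0.0016) and the latter, on an estimate of 0.19 fragments, was not called (Cuffdiff q = 0.23). In the JAK-STAT list, AGAP000099 (X, 1585208 to 1626407) stood at 11.6 FPKM and was 2.60-fold lower in the authors' deposited table (Cuffdiff q = 0.00012), and AGAP010423 (3L, 3092566 to 3094734) was listed at 0. The Toll and the JAK-STAT list each had 1 locus called lower and 0 higher in the authors' deposited table, and adjusted over the list alone the counts were the same. The levels of the IMD and Toll lists (permutation test, adjusted p = 0.14 and 0.41), their ratios (0.78 for each) and their expressed shares (Fisher's exact test, adjusted p = 0.42 and 1) did not pass. The IMD level passed with estimated counts in place of FPKM (permutation test, adjusted p = 0.042, range 0.042 to 0.35 over 7 alternatives). The 8 signalling loci ranked 0.76 percentile points from the 5 antimicrobial effectors (exact permutation test, two-sided, adjusted p = 0.98).

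All 9 loci of the small RNA list, the machinery of RNA interference, were expressed in Ag55, against 55.8% of other loci (Fisher's exact test, adjusted p = 0.047). This call was lost at thresholds of 0.1, 0.5, 5 and 10 FPKM (Fisher's exact test, adjusted p = 0.43, 0.12, 0.16 and 0.24). The share was still 100% at 0.1 and 0.5 FPKM. Against loci with an AGAP ID the call was kept (Fisher's exact test, adjusted p = 0.037). Among the siRNA and miRNA genes, AGAP009887 (3R, 44748943 to 44754520) was highest at 52.9 FPKM with a relative model SD of 23.0%, followed by AGAP011717 (3L, 32095282 to 32132641) at 16.9 FPKM and AGAP008887 (3R, 20286712 to 20295205) at 12.2 FPKM. In the authors' deposited table the first was 4.18-fold and the second 1.61-fold higher in Ag55 (Cuffdiff q = 0.00012 and 0.0046), and the third was lower, at a log2 ratio of -1.32 (Cuffdiff q = 0.00012). Among the piRNA genes, AGAP011204 (3L, 19302187 to 19317357) reached 157 FPKM, AGAP008578 (3R, 13260489 to 13264639) 13.7 FPKM and AGAP009509 (3R, 34973039 to 34981807) 7.02 FPKM, the last with a relative model SD of 104%. AGAP011204 was 6.24-fold higher in Ag55, AGAP008578 20.9-fold lower and AGAP008862 6.96-fold lower in the authors' deposited table (Cuffdiff q = 0.00012 each). Over the 9 loci, the authors' deposited table called 3 higher and 3 lower, with the same counts adjusted over the list alone. The siRNA and miRNA part held 2 higher and 1 lower in the authors' deposited table and adjusted over the list alone. The piRNA part held 1 higher and 2 lower in the authors' deposited table, and 1 and 3 adjusted over the list alone. The added locus was AGAP009509 (Cuffdiff p = 0.047 in the authors' deposited table), which was not called when adjusted over the 9 loci. The levels of the list and of its siRNA and miRNA and its piRNA parts (permutation test, adjusted p = 0.26, 0.34 and 0.34) and their ratios (0.97, 0.97 and 0.78) did not pass. The expressed shares of the parts, 100% in each, did not pass Fisher's exact test (adjusted p = 0.28 for each). The parts differed in rank by -0.81 percentile points (exact permutation test, two-sided, adjusted p = 0.98). The ribosomal protein list held a single ID, AGAP010592 (3L, 6565273 to 6566713), at 4232 FPKM, which was 10.8-fold higher in Ag55 in the authors' deposited table (Cuffdiff q = 0.00012).

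**Figure D1:**
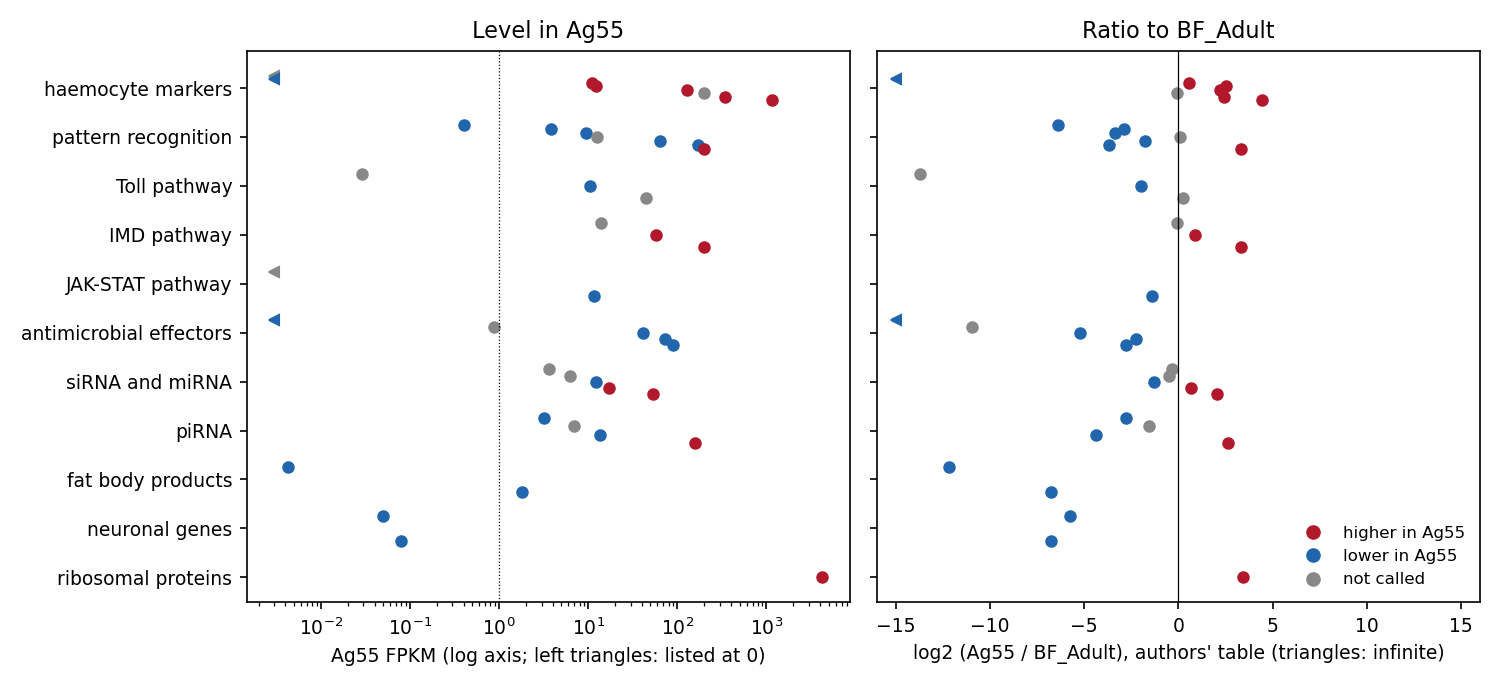
Ag55 level in FPKM on a log axis (left, dotted line at 1 FPKM) and log2 ratio of Ag55 over BF_Adult in the authors' deposited table (right) of each locus in the fixed lists, coloured by the authors' call, offset vertically to stay visible, with triangles for levels of 0 and infinite ratios, and without error bars since values are pooled. Of the 8 haemocyte loci 5 were called higher in Ag55, and of the 5 antimicrobial effectors 4 were called lower. Of all tested loci, 62.9% were called. The median ratio of neither list passed against random lists (permutation test, adjusted p = 0.55 for each).

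Over the whole genome, the authors' deposited table called 7771 loci at a q under 0.05, which is 62.9% of the 12357 tested, with 3782 higher and 3989 lower in Ag55. Among called loci, differences of at least 10-fold numbered 2073 toward lower and 1260 toward higher levels in Ag55 in the authors' deposited table. These counts include 1009 loci listed at 0 in Ag55 and 824 listed at 0 in BF_Adult, which have no finite fold. The median log2 ratio of all tested loci, BF_Adult over Ag55, was 0.26 in the authors' deposited table. Outside the lists, AGAP007087 (2L, 42327400 to 42406342) and AGAP007740 (3R, 172973 to 173928) had the highest levels among loci of a single ID called higher with a finite ratio, at 31792 and 17751 FPKM. They were 19.1-fold and 18.4-fold higher in Ag55 in the authors' deposited table. Among single-ID loci at 1 FPKM or more, AGAP007165 (2L, 43749619 to 43750588) and AGAP008988 (3R, 22729632 to 22733488) were furthest below BF_Adult, 423-fold and 341-fold lower in the authors' deposited table (Cuffdiff q = 0.00012 for all 4). These 4 IDs were chosen after their values were seen. Of 19730 transcripts tested, the authors' deposited table called 3519 higher and 3429 lower in Ag55. In 57 of the 6460 loci with a called transcript, transcripts were called in both directions in the authors' deposited table. Of these 57 loci, 10 merge more than 1 AGAP ID, so their opposite calls may belong to different genes.

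Loci without an AGAP ID differed in direction between placed and unplaced sequence. On unplaced sequence (named UNKN in the tables), 596 of 1443 such loci (41.3%) were called higher in Ag55 and 144 (9.98%) lower in the authors' deposited table. On the 5 placed arms, 500 of 2381 (21.0%) were called higher and 746 (31.3%) lower in the authors' deposited table. The share called higher in the authors' deposited table differed between them (Fisher's exact test over loci, adjusted p = 3.6e-40). These shares are over all such loci, tested or not. At 1 FPKM or more in Ag55 stood 80.9% of the unplaced and 52.1% of the placed loci. A difference in expression thus enters this test, which also takes neighbouring loci as independent units. Among loci at 10 FPKM or more the shares called higher in the authors' deposited table, 65.5% and 60.8%, did not pass (Fisher's exact test, adjusted p = 0.25), where the filter on the Ag55 level itself favours higher calls in both. Of the loci with an AGAP ID, 20.3% were called higher and 23.4% lower in the authors' deposited table. Those of them on unplaced sequence were called higher in 94 of 580 (16.2%) and lower in 42 (7.24%) in the authors' deposited table.

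**Figure D2:**
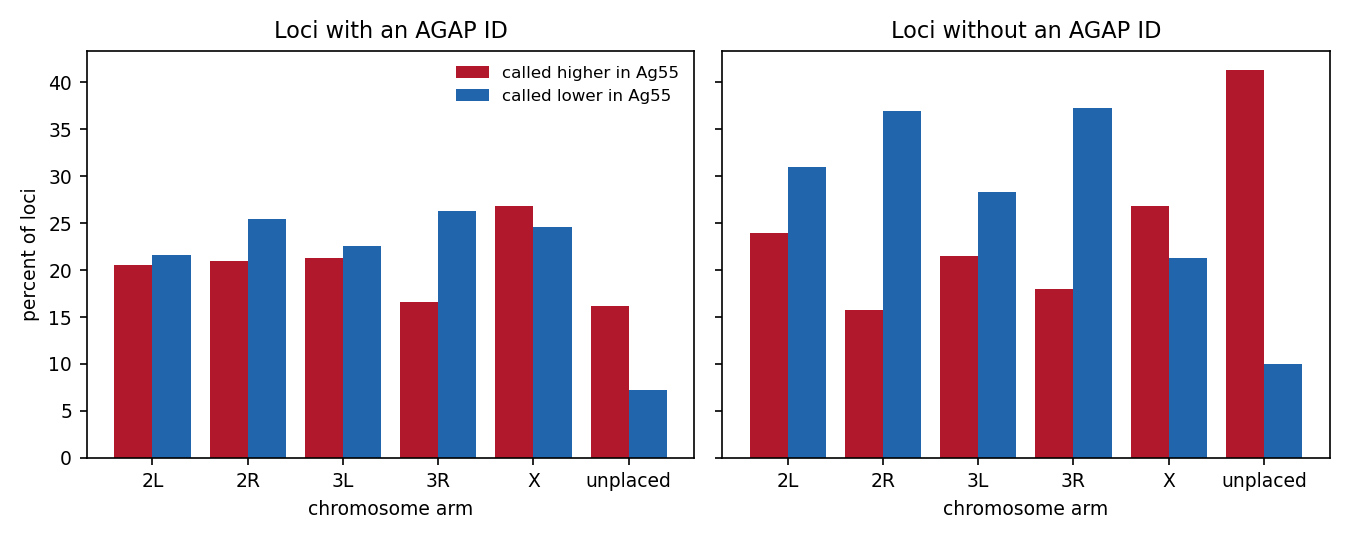
Percent of loci (y axis, from 0) on each chromosome arm and on unplaced sequence that the authors' deposited table called higher or lower in Ag55 than in BF_Adult, for loci with an AGAP ID (left) and without (right), as shares without error bars. Unplaced loci without an ID had 41.3% called higher and 9.98% lower.

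Chromosome arms also differed. Among tested loci at 1 FPKM or more, the median log2 ratio from the authors' deposited table was 0.60 above the other arms on X and differed by -0.33 on 3R (permutation of loci over arms, adjusted p = 0.0012 for each, from p = 0.0005, the smallest that 2000 permutations can give). With loci that carry an AGAP ID alone, X differed by 0.24 in the authors' deposited table (permutation test, adjusted p = 0.018, range 0.0012 to 0.018 over 2 alternatives). With all tested loci 3R differed by -0.62 in the authors' deposited table. Arm 2R differed by -0.15 in the authors' deposited table (permutation test, adjusted p = 0.028), a call lost with loci that carry an ID (-0.025) and with all tested loci (-0.023; permutation test, adjusted p from 0.64 to 0.78). Arms 3L and 2L, at 0.15 and 0.10 in the authors' deposited table, did not pass (permutation test, adjusted p = 0.051 and 0.17), but 3L did with loci that carry an ID (0.18; permutation test, adjusted p from 0.018 to 0.24 over 2 alternatives). Neighbouring loci are not independent units, which these permutations do not take into account.

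Along the arms, the median ratio of 2 Mb windows differed by more than in shuffles of the loci over all arms. Differences between arms enter this spread, since the loci were not shuffled within each arm. The medians of 111 windows, from the authors' deposited table, had an SD of 0.91 log2 units, above each of 2000 shuffles of the loci over positions, whose highest SD was 0.68. Each alternative has shuffles of its own. With all loci the SD was 1.58, against a highest shuffle of 0.60. With 1 locus per 50 kb it was 1.46, barely above the highest shuffle, also 1.46. After correction for the Ag55 level it was 0.51, against a highest shuffle of 0.22. Of the 111 windows, 10 lay higher in Ag55 and 9 lower than the shuffles allow. In the authors' deposited table the highest medians were 1.76 at 48000001 to 50000000 on 2L, 1.75 at 2000001 to 4000000 on 2L, 1.56 at 1 to 2000000 on 3L and 1.48 at 58000001 to 60000000 on 2R. The lowest median among windows beyond the shuffles was -2.51 at 34000001 to 36000000 on 2R, where 14 of 87 loci were called higher and 40 lower in the authors' deposited table. These shares were 16.1% and 46.0%, against 28.9% and 34.1% over the 8962 loci of the window test. The genome-wide median log2 ratio of these loci, BF_Adult over Ag55, was 0.41 in the authors' deposited table, so window medians are not centred on 0. A run of 13 neighbouring loci with an AGAP ID on 2L (3026512 to 3070456) was called higher in Ag55 throughout, by a median of 5.12-fold, in the authors' deposited table. In 1000 shuffles of the calls the longest such run was 10. That run lies in the 2L window at 2000001 to 4000000, where 60.2% of loci were called higher in the authors' deposited table. It is thus not separate from the result of that window, and the test of runs was chosen after its result was seen.

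**Figure D3:**
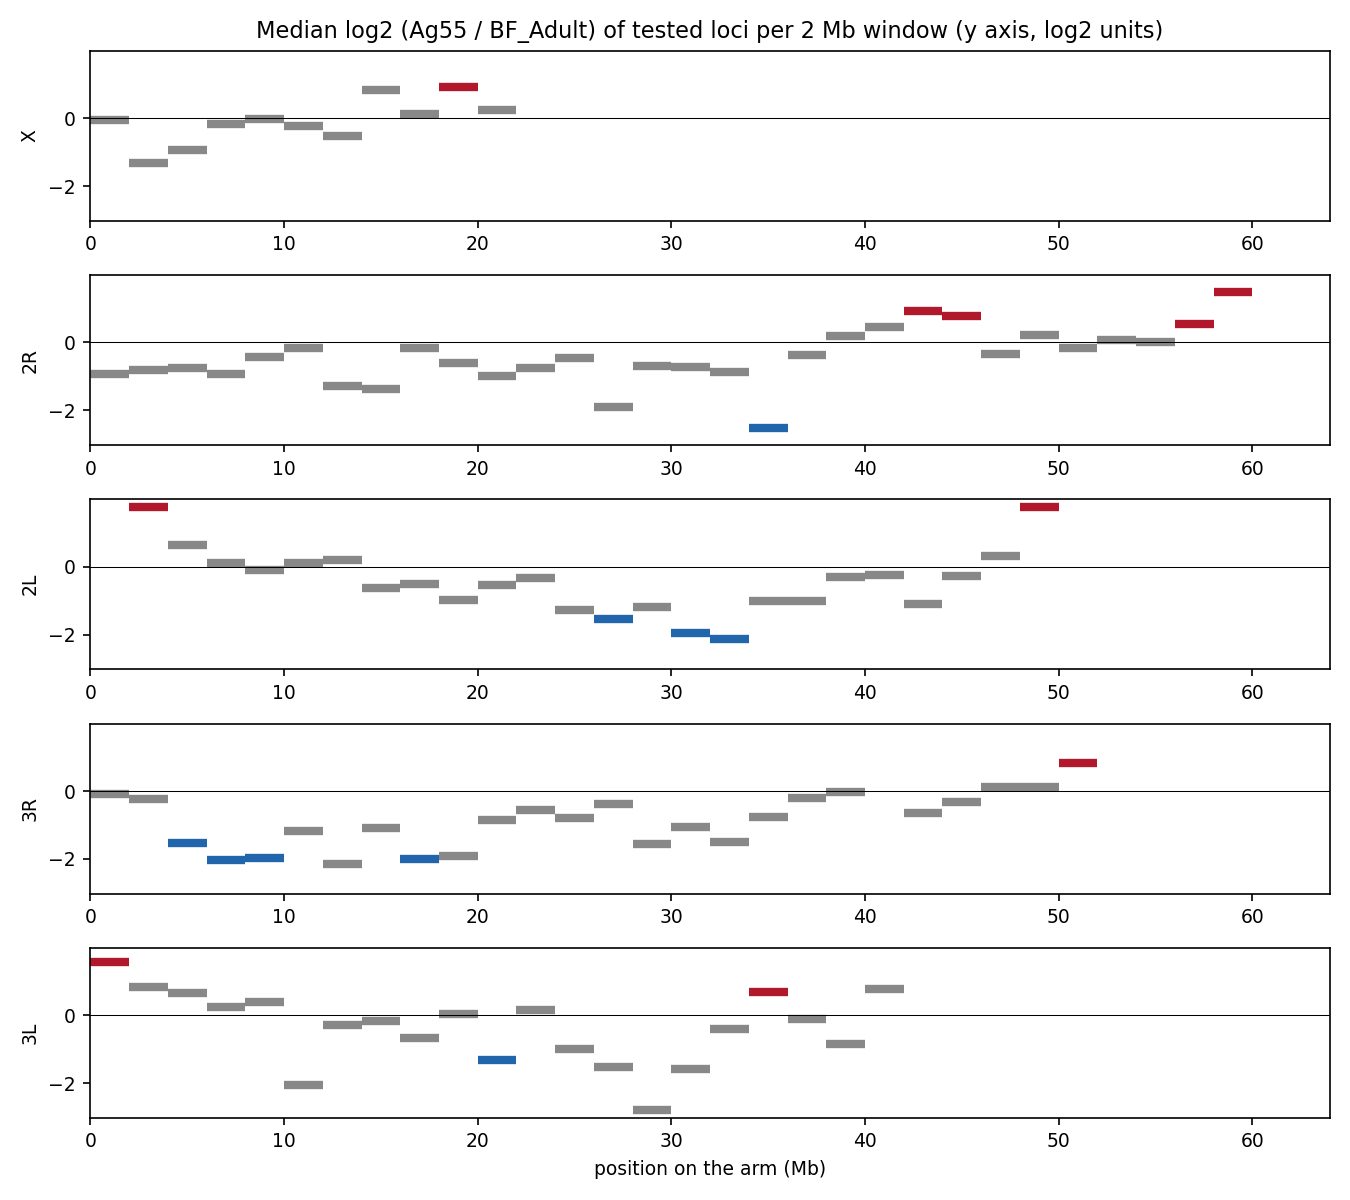
Median log2 ratio of Ag55 over BF_Adult (y axis) of tested loci with an AGAP ID in 2 Mb windows along each chromosome arm (x axis, Mb), from the authors' deposited table, with windows higher (red) and lower (blue) in Ag55 than shuffles allow and the others in grey. Medians of 1.75 on 2L, 1.56 on 3L and 1.48 on 2R stood near ends of those arms, and 1.76 near the other end of 2L. The line at 0 is not the genome-wide median, which was 0.41 as BF_Adult over Ag55.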

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

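Alternatives on arms, windows, merged loci, loci without an ID and BF_Adult, and on expressed loci with an AGAP ID, were chosen after seeing the data. The number of expressed loci stayed within 1.5 times of its value in 7 alternatives and fell to 5048 at 10 FPKM, and loci with several expressed transcripts fell to 1513 at 5 FPKM, since fewer pass. The haemocyte list (median log2 level 5.33) lost its call against loci with an AGAP ID (permutation test, adjusted p = 0.086), and without merged loci, at 3.64 (0.25; permutation test, adjusted p from 0.011 to 0.25 over 7 alternatives). The antimicrobial effector list (5.38) passed with a background matched on span, and the IMD list with estimated counts (10.25), with adjusted p from 0.044 to 0.35 and from 0.042 to 0.35 in permutation tests over 7 alternatives each; the cause was not tested. Another 50 alternatives on list levels, 36 on expressed shares, 15 on list ratios and 19 on list contrasts kept their side of the threshold, though 1, 1, 1 and 4 of these values, none of them called, changed sign. The expressed share of the small RNA list was 100% at 0.1 and 0.5 FPKM, 77.8% at 5 and 55.6% at 10 FPKM, without a call (Fisher's exact test, adjusted p from 0.037 to 0.43 over 5 alternatives, the lowest against loci with an AGAP ID, where the call was kept). Arm 2R differed by -0.025 with loci that carry an ID and by -0.023 with all tested loci, without a call, and 3L by 0.18 with loci that carry an ID, with a call; the cause was not tested. Unplaced loci without an ID were called higher in 65.5% at 10 FPKM or more, where the difference from placed loci did not pass, under a filter that itself favours higher calls in both. The number of loci called in the authors' deposited table ranged from 5785 with an AGAP ID to 6834 at 2-fold or more (centring the ratios cannot change it), the isoform table called 6948 transcripts, and the SD of window medians from 0.51 to 1.58 log2 units, above the shuffles each time but barely so with 1 locus per 50 kb. Not run, for want of values per replicate or of the second condition's FPKM, were leaving out a replicate, replicate agreement, differences between replicates and a filter on both sides. The background of genes with a symbol was replaced by loci with an AGAP ID. Leaving out ribosomal RNA and mitochondrial genes was not run, since no name marks the former and the latter were not estimated. The contrast of haemocyte and neuronal loci at 1 FPKM or more has no neuronal locus left. No paired analysis was possible because the series has a single group and its values are pooled. At the low end, 922 tested loci with a finite log2 ratio of at least 5 toward BF_Adult were not called in the authors' deposited table, at a median Ag55 level of 0.060 FPKM against 0.25 FPKM in those called; the effect of depth was not tested.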

Other observations

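The arm, window and unplaced patterns were noticed in the data and then tested on the same data, and the tests of runs, of locus assembly and of position along the arm were chosen only after their results were seen. After the values were seen, 2 criteria of the window tests and that of locus assembly were also made stricter, as given with them.

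Besides the run of 13 loci on 2L, other runs of neighbouring loci were called alike, some of them sharing bundles of overlapping transcripts. A run of 9 loci on 2R (58623975 to 58676176) was called higher in Ag55 in the authors' deposited table, by a median of 3.65-fold, and 7 of 1000 shuffles gave a run as long. These 9 loci lay in 6 bundles, within the 2R window at 58000001 to 60000000 that itself lay higher in Ag55. On X, 8 loci (15327411 to 15388601) were called higher by a median of 4.20-fold in the authors' deposited table, with 31 of 1000 shuffles as long. The longest runs called lower held 8 loci, on 2R (20538758 to 20608709) and on X (5466762 to 5616769), in the authors' deposited table, and 113 of 1000 shuffles gave a run as long. Each of these lower runs lay in 7 bundles. Of the loci called higher in Ag55 that were listed at 0 in BF_Adult in the authors' deposited table, 756 carried no AGAP ID and 68 did. Of those called lower and listed at 0 in Ag55 in the authors' deposited table, 576 carried none and 433 did.

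Windows of 2 Mb differed in their ratio to BF_Adult. A dependence of the ratio on the Ag55 level was not the whole cause: after correction in 20 bins of FPKM, the SD of window medians was 0.51 log2 units, against at most 0.22 in 500 shuffles. Tandem families or overlapping loci stay open, since with 1 locus per 50 kb the SD of 1.46 lay barely above the highest of 500 shuffles, also 1.46; as first set, the criterion would have excluded them, and a margin of the shuffles' SD was then required. A regional gain of DNA copies in Ag55 may contribute, and a loss was not examined. The 5 windows highest in Ag55 over odd-numbered loci were chosen. Of their held-out loci below the median Ag55 FPKM, 65.2% had a ratio on the Ag55 side of the genome-wide median (exact 95% interval 52.8 to 76.3). Above the median FPKM the share was 77.1%. The interval takes neighbouring loci as independent, so it may be too narrow. Both shares met the 65% first set, but the interval reaches under the 55% then also required. Shared regulation of neighbours would give the same, so the explanation was left open. No biological explanation that the study's groups would give was tested, since the design has a single group.

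The window medians may also follow position, with higher values toward the ends where 2R meets 2L and 3R meets 3L and the high-coordinate end of X. The mean over the 5 arms of Spearman's rho across windows, between ratio and distance from that end, was -0.51, from -0.24 on 2L and -0.33 on 3L to -0.57 on 3R, -0.69 on 2R and -0.72 on X, and 7 of 2000 rotations of the windows within arms gave a mean as low. Windows are not independent replicates, this gradient is a hypothesis found on the same data, and windows toward the other end of 2L (1.76) and of 3L (0.68 at 34000001 to 36000000 and 0.76 at 40000001 to 42000000) do not follow it.

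Chromosome arms differed as well. A gain or loss of a whole arm could not be decided. Among tested loci at 1 FPKM or more, X departed most. It did so by 0.81 log2 units below the median Ag55 FPKM and by 0.36 above it, and the latter is under the 0.4 set beforehand. In both alternatives 3R departed more than X. The values were -0.29 against 0.24 with loci that carry an AGAP ID and -0.62 against 0.49 with all tested loci. The number of X copies in Ag55 and the sexes in BF_Adult are not given in the sources used here, so a difference in X dose stays open.

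Unplaced loci without an AGAP ID were more often called higher in Ag55 than lower. Locus models built from Ag55 reads stay open: such loci on placed arms were called higher in 21.0% and lower in 31.3% in the authors' deposited table, which excluded this under the criterion as first set, but these are the loci the pattern is set against, and at 10 FPKM or more they were higher in 60.8% and lower in 6.65%. Loci near the detection floor stay open too: at 10 FPKM or more 65.5% of unplaced loci were called higher in the authors' deposited table, but a filter on the Ag55 level itself favours higher calls in both sets, so this decides nothing. Repeated sequence, strain differences and RNA of other origin were not tested, because no sequence was used for these loci.

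Of 1830 tested loci with a finite log2 ratio of at least 5 in either direction, 1191 were not called in the authors' deposited table, 922 of them lower and 269 higher in Ag55.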
